A study of Homo sapiens with 4 samples.

How the data were processed

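In situ Hi-C maps of 4 human colon cancer cell lines were analysed, 1 library per line. Hi-C joins DNA ends that lie close together in the nucleus and counts the joined pairs, so that each pair of genome segments receives a contact value. The chromatin was digested with the restriction enzyme MboI, per the labels' protocols. The submitters' processing notes name BWA, Picard and the genome build hg19, with no role or order; versions and the balancing tool are not given in the sources used here.

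Each deposited file lists pairs of 40 kb bins with a signal value that is never negative, and the authors' table of bins gives each bin's chromosome, start and end. The labels do not state how the values were normalised, so this was worked out from the values. In CaCo2 the sums of the deposited signal per bin were equal over the genome, with a coefficient of variation of 0.000317%. In SW480, DLD1 and LoVo the sums were level within each chromosome, with SDs of 0.0846%, 0.0615% and 0.0968%, and differed between chromosomes by coefficients of variation of 14.9%, 12.0% and 17.0%. The deposited values are therefore balanced and are not counts, and the CaCo2 map was balanced over a different set of contacts from the other 3.

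Balancing multiplies a whole number of contacts by a factor for each of its bins. These factors were estimated from the deposited values, and dividing by them gave values within 0.05 of a whole number for 99.948% of the off-diagonal pairs in SW480, 99.968% in DLD1, 99.983% in LoVo and 99.774% in CaCo2. The rounded numbers are called recovered contacts. They are estimates from the deposited values and not the authors' own counts. Their totals were 163182479 in SW480, 215582856 in DLD1, 123765823 in LoVo and 148107013 in CaCo2. On 175475 simulated pairs the same procedure recovered 100% of the whole contacts.

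Chromosomes 1 to 22 and X were analysed. A 40 kb bin was usable where its recovered contacts reached 20% of the median in every map, which kept 69181 of 75918 bins. Arms were split at the longest stretch of bins without contacts. On chromosome 6 this stretch, from 28480001 to 32520000, lay on the short arm, so the next longest was used there, a departure from the rule fixed before the data were examined.

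Contact decay was the slope of log10 mean deposited signal on log10 distance from 400 kb to 20 Mb over autosomes. Compartment scores were computed per arm in 200 kb bins. Contacts were balanced with 40 iterations and divided by the mean at their distance. Values above the 99.9th percentile were set to it. Of the first 3 eigenvectors of the correlation matrix, the one closest to an orienting track was taken and scaled to an SD of 1 per line. The track was the log ratio of contacts with chromosomes 16, 17, 19, 20 and 22 over those with 4, 5, 6, 13 and 18. A positive score marks the group of segments that, over the 4 maps together, tends to contact the first, gene-rich set more. Scores were computed from contacts within the arm, so they do not measure the contacts of 1 line with gene-rich chromosomes. Most contacts behind the track come from the CaCo2 map. A line-specific region was a run of at least 2 bins in which 1 line had the opposite sign to the other 3 and lay at least 1 score unit from each.

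Insulation was the log2 mean balanced contact in a 480 kb window over the mean of the chromosome, and a boundary was a local minimum with a prominence of at least 0.2. Boundaries matched within 1 bin. Chance was estimated from 200 circular shifts of at least 25 usable bins. Coverage was the share of a line's recovered contacts in each 1 Mb bin with at least 15 usable 40 kb bins, as a log2 ratio over the median of the 4 lines, centred on autosomes. Coverage had been planned only for unbalanced values. It was run on recovered contacts as an analysis added after the data were seen. Clusters between chromosomes were groups of at least 4 pairs of 1 Mb bins, each with at least 20 recovered contacts, at least 5 times the number expected from the coverage of both bins, and under 2 times in each other line.

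With 1 library per line there is no estimate of the spread between cultures, so no test of a difference between lines was run and no p-value is given. Summary values were screened only for a line far from the other 3, with Dixon's ratio of the gap to the range against its 95% critical value for 4 samples. Exact 95% intervals, binomial for shares and Poisson for counts, and 3 random splits of each map into equal parts cover counting error only. For shares of boundaries and regions, the binomial intervals treat each boundary or region as an independent trial. They do not cover error in calling or matching them. Choices listed as planned were made before the data were examined.

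The regions named were fixed by rule: per line the 3 line-specific regions of each sign with the greatest distance to the nearest other line, the 3 highest and 3 lowest arms beyond 0.3 in coverage, the 3 most extreme coverage runs beyond 1, the 3 clusters with the most contacts above expectation, and the 3 boundaries of greatest prominence found in that line only. The gene table used here is on another genome build, so gene lists were not placed on the maps and no gene was scored. In simulated maps, 100% of 40 seeded boundaries, 100% of 10 switched compartment regions and 100% of 5 clusters were recovered, and 0% of the called regions lay at unseeded places. The clusters were simulated at a background close to that of CaCo2, 9.62 contacts per pair of 1 Mb bins. SW480, DLD1 and LoVo held 0.0799, 0.0945 and 0.0622, so recovery of clusters in such sparse maps was not tested. Alternatives covered bin size, balancing, depth, thresholds and reference. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.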

Results

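Genome-wide chromatin contacts were mapped in SW480, DLD1, LoVo and CaCo2, established lines grown from human colorectal cancers. The series title concerns somatic mutations and chromatin structure. The maps allow the lines to be compared in contact decay, compartments, domain boundaries, coverage and contacts between chromosomes. Each line had 1 library, so every difference below is between 4 maps. Positions are in hg19.

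DLD1 had the deepest map, with 215582856 recovered contacts, followed by SW480 with 163182479, CaCo2 with 148107013 and LoVo with 123765823. Contacts between different chromosomes made up 28.8% of the CaCo2 map (exact binomial interval 28.80 to 28.81). They made up 0.218% of the SW480 map (0.217 to 0.219), 0.195% of the DLD1 map (0.195 to 0.196) and 0.224% of the LoVo map (0.223 to 0.225). Within chromosomes the depths were 162826698 in SW480, 215161429 in DLD1, 123488406 in LoVo and 105441338 in CaCo2.

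Contacts fell most steeply with distance in DLD1 and least steeply in LoVo. The slope from 400 kb to 20 Mb was -1.20 in DLD1, -1.16 in SW480, -1.15 in CaCo2 and -1.08 in LoVo, with SDs over autosomes of 0.0409, 0.0296, 0.0220 and 0.0332. DLD1 had the steepest slope on 22 of 22 autosomes, and LoVo the flattest on 20, with CaCo2 flattest on the other 2. Of the signal over 80 kb apart, 62.3% spanned under 2 Mb in DLD1, 59.6% in SW480, 57.6% in CaCo2 and 54.8% in LoVo. Beyond the fitted range the order changed, and CaCo2 had the largest share of contacts at 100 Mb or more, 1.92%, against 1.29% to 1.405% in the other 3 lines.

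**Figure D1:**
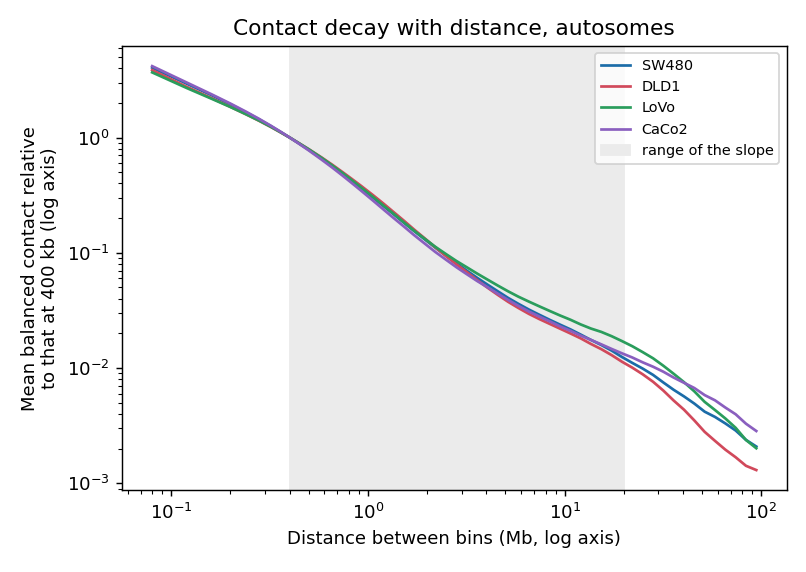
Mean balanced contact (vertical axis, relative to that at 400 kb, log scale) against the distance between bins in Mb (horizontal axis, log scale), 1 curve per line, with the fitted range shaded. The LoVo curve lies above the others near 10 Mb, with a slope of -1.08 over the shaded range, and DLD1 is lowest at 20 Mb, with a slope of -1.20.

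Compartments, the division of the genome into active and inactive segments that contact their own kind, were largely shared. The closest pair was DLD1 and LoVo, with a correlation of 0.899 over 13881 bins of 200 kb. The most distant was SW480 and DLD1, at 0.861, and the other pairs lay between 0.869 and 0.880. The same sign was found in 85.8% of bins for SW480 and DLD1 and in 88.8% for DLD1 and LoVo. Random parts of 1 map correlated at 0.993 in SW480, 0.993 in DLD1, 0.993 in LoVo and 0.977 in CaCo2, above every pair of lines. On chromosome 22 the CaCo2 scores were unreliable: parts of its map correlated there at 0.000181, against 0.971 in SW480, 0.906 in DLD1 and 0.820 in LoVo. SW480 was scored there by the first eigenvector and the other lines by the second, and it correlated with them at 0.216 to 0.230, while DLD1 and LoVo correlated at 0.833.

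A total of 118 regions, 67.6 Mb or 2.43% of the 2776.2 Mb scored, had a compartment found in 1 line only. SW480 had 32 regions with a positive score and 10 with a negative score, DLD1 had 22 and 1, LoVo had 7 and 17, and CaCo2 had 18 and 11. In SW480 the 800 kb region of 18q from 75.4 to 76.2 Mb scored 1.13, against -1.25 in DLD1, -0.78 in LoVo and -0.82 in CaCo2. The 16q region from 50.8 to 51.8 Mb scored 0.65 in SW480 and -1.21 to -1.35 in the others, and the 6q region from 125.6 to 126.0 Mb scored 1.24 in SW480. Regions with a negative score in SW480 were on 7p from 16.8 to 17.2 Mb, at -0.44, and on 6q from 130.6 to 131.2 Mb, at -1.002. A region of 22q from 26.2 to 26.6 Mb met the rule in SW480 at -1.63, but parts of the CaCo2 map differed there by 2.33 score units, and the difference was lost under 3 of 4 alternatives.

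In DLD1 the 13q region from 94 to 95 Mb, the 20q region from 45.4 to 45.8 Mb and the 5p region from 32.8 to 33.4 Mb were positive and negative in the other 3 lines. At these settings the only negative region of DLD1 was on 10p from 4.8 to 5.4 Mb. There were 9 with 400 kb bins, 3 at a 50% coverage minimum and 2 on recovered contacts. With 400 kb bins, 1 bin was enough for a region, so the rule changed along with the bin size. The 10 negative regions of SW480 became 21 with 400 kb bins and 6 on recovered contacts. LoVo was alone in a positive score on 1q from 233.6 to 234.2 Mb and on 13q from 89.2 to 89.8 Mb and from 90.2 to 90.6 Mb. It was alone in a negative score on 3p from 64.0 to 64.6 Mb, on 12p from 5.0 to 5.8 Mb and on Xp from 10.2 to 10.6 Mb, and the Xp difference changed sign when bins under 50% of the median coverage were left out. CaCo2 was alone in a positive score on 8p from 24.0 to 24.6 Mb, 7p from 21.4 to 21.8 Mb and 13q from 76.6 to 77.0 Mb. Its negative regions included 17q from 63.0 to 64.2 Mb, where it scored -1.37 against 0.70 to 0.77 elsewhere, 7p from 46.0 to 46.8 Mb and 6q from 128.8 to 129.8 Mb. Random parts of 1 map were compared by a looser rule, opposite signs and a distance of at least 1 over at least 2 bins. It gave at most 1 region in SW480 and 0 in DLD1 and LoVo. It gave up to 17 in CaCo2, and 0 once chromosomes 21 and 22 were left out. Each part has fewer contacts than the whole map, so these numbers are not on the same footing as those between lines. The total was 223 with 400 kb bins, where 1 bin was enough, and 29 at a distance of 1.5.

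**Figure D2:**
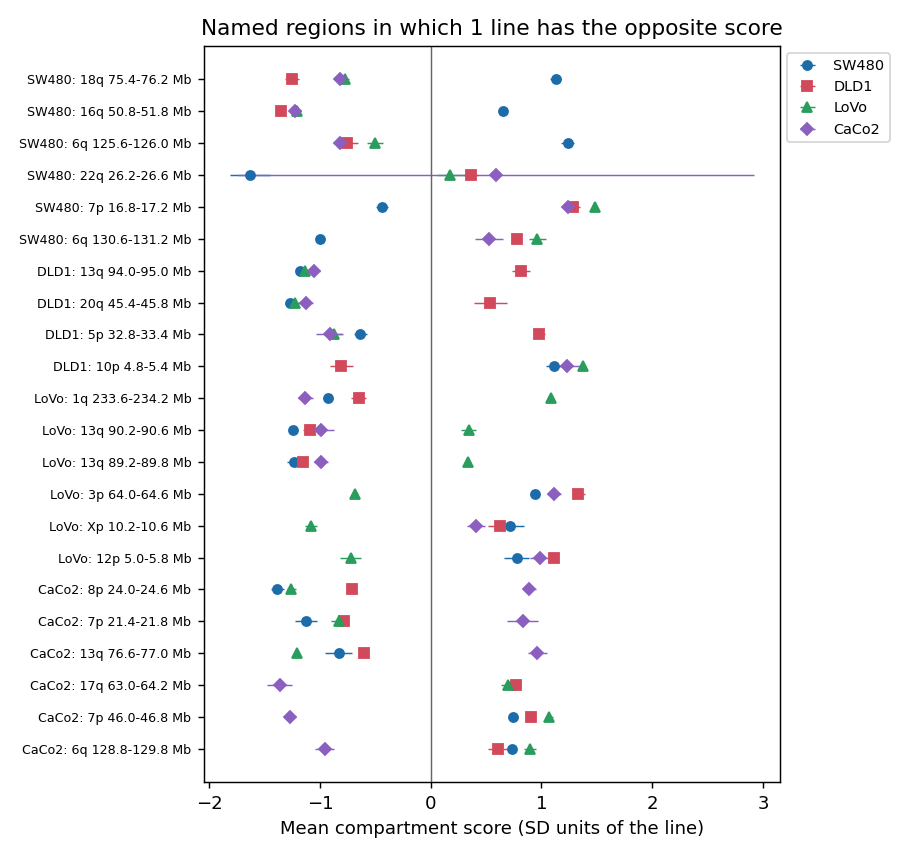
Mean compartment score (horizontal axis, in SDs of the line) of each named region (rows, headed by the line that stands apart), with 1 marker per line and bars for the mean absolute difference between random parts of its map. In SW480 the 18q region from 75.4 to 76.2 Mb scored 1.13 while the other lines were negative, and on 22q the CaCo2 bar spans 2.33 units.

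Domain boundaries were mostly common to the lines. There were 3853 in SW480, 3649 in DLD1, 3496 in LoVo and 3869 in CaCo2. All 4 lines shared 62.9% of the SW480 boundaries (exact binomial interval 61.4 to 64.4), 66.1% of those of DLD1 (64.5 to 67.6), 69.0% of those of LoVo (67.4 to 70.5) and 62.4% of those of CaCo2 (60.9 to 64.0). Between pairs of lines the match ran from 73.7%, CaCo2 boundaries found in LoVo, to 84.4%, LoVo boundaries found in SW480. Shifted positions matched at 16.1% on average and at most 18.5%, and random parts of 1 map matched at 90.1% to 94.4%. Each part has fewer contacts than the whole map, so the last range is a floor.

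CaCo2 had the most boundaries of its own, 429 or 11.1% (10.1 to 12.1), against 294 in SW480, 246 in DLD1 and 217 in LoVo. Boundaries found in 1 line were shallower, with a median prominence of 0.293 in SW480 against 0.922 for those shared by all, and 0.354 against 0.867 in CaCo2. Among the named ones, the SW480 boundary on chromosome 5 from 93800001 to 93840000 stood apart most clearly. Its insulation was -1.24 in SW480, against 0.16 in DLD1, 0.13 in LoVo and -0.14 in CaCo2, and the nearest boundary of another line was 400 kb away. LoVo had a boundary on chromosome 7 from 56360001 to 56400000, at -1.05 against -0.16 to -0.46. CaCo2 had one on chromosome 6 from 4000001 to 4040000, at -0.95 against -0.46 to -0.61. At the other named boundaries the insulation differed less from that of the nearest line. The LoVo boundary of greatest prominence, on chromosome 12 from 125600001 to 125640000, was at -0.88 in LoVo and lower in the others, at -0.93 to -0.94. The LoVo boundary on chromosome 20 from 54920001 to 54960000 was at -1.04, against -1.01 in DLD1. The 3 named DLD1 boundaries lay 80 kb from a boundary of another line. The one on chromosome 6 from 58040001 to 58080000 was at -1.36 in DLD1 and lower in SW480, at -1.41. Those on chromosomes 4 and 18 were at -1.25 and -1.27 in DLD1, against -1.09 and -1.14 in SW480. In CaCo2 the boundary on chromosome 15 from 84920001 to 84960000 was at -1.47, against -1.28 in LoVo, and that on chromosome 2 from 118760001 to 118800000 at -1.08, against -0.94 in SW480. The SW480 boundaries on chromosome 2 from 161920001 to 161960000 and chromosome 6 from 112480001 to 112520000 were at -1.09 and -1.24, against -0.92 in CaCo2 and -1.02 in DLD1.

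**Figure D3:**
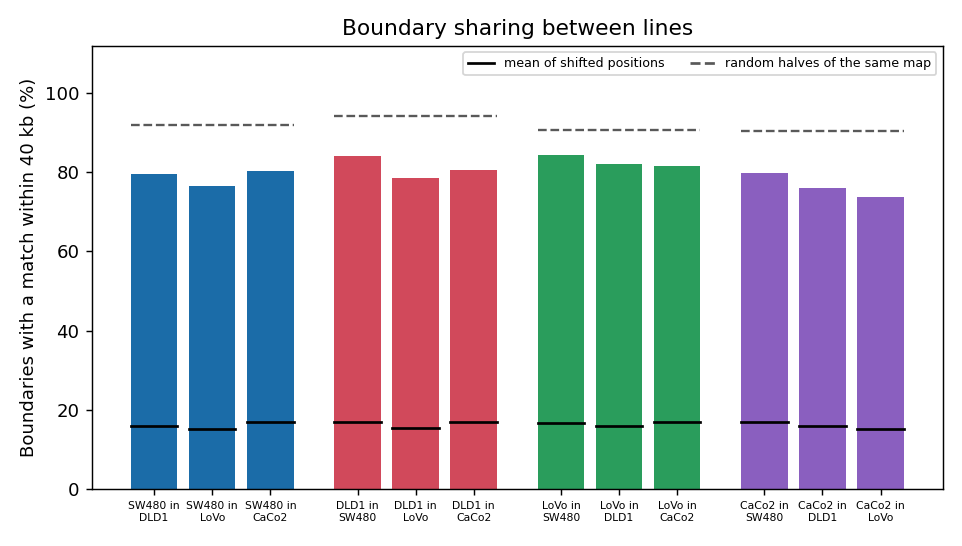
Percent of the boundaries of 1 line (first name under each bar) with a boundary of another line (second name) within 40 kb, with the mean of shifted positions as a black line and random parts of the same map as a dashed line. The bars run from 73.7% to 84.4%, above the shifted positions and below the random parts.

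Boundaries lay at a change of compartment more often than shifted positions did in all 4 lines. The share was 32.1% in LoVo (exact binomial interval 30.6 to 33.7), 28.6% in DLD1 (27.1 to 30.1), 25.8% in SW480 (24.5 to 27.2) and 24.9% in CaCo2 (23.6 to 26.3). Shifted positions gave means of 21.01% in LoVo, 19.8% in DLD1, 17.97% in SW480 and 18.1% in CaCo2. The ratios to these were 1.53 in LoVo, 1.45 in DLD1, 1.44 in SW480 and 1.38 in CaCo2.

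Contact coverage, used here as a guide to DNA copy number, was taken from all contacts, and in CaCo2 alone these include a large share between chromosomes. Copy number was not measured in another way, and whether coverage also differs with compartment was not tested. Of 41 arms, 10 in CaCo2 lay at or beyond 0.3 on the log2 scale, against 4 in SW480, 3 in DLD1 and 4 in LoVo. With contacts within chromosomes only the CaCo2 number was again 10, but the arms differed. Among arms chosen after their values were seen, CaCo2 22q went from 0.37 to 0.15, 17p from -0.29 to -0.50 and 17q from 0.57 to 0.40. In CaCo2 coverage was highest on 20q (log2 ratio 0.97, 1.963-fold the median of the lines), 11q (0.79) and 10p (0.62), and lowest on 18q (-0.83), 1p (-0.54) and 9p (-0.38). LoVo was highest on 5p (0.82, 1.76-fold) and 12q (0.38) and lowest on 20q (-0.47) and 19q (-0.34). SW480 was highest on Xp (0.65), Xq (0.59) and 21q (0.34), and DLD1 was lowest on 12p (-0.44), 7p (-0.33) and 7q (-0.31). A change common to several lines is not measured by this ratio, and a line without it can look low. The median deposited signal per bin of DLD1 was 5593 on chromosome 7 and 5892 on chromosome 12. Its autosomes ran from 4853 to 6336. Chromosome 7 was the highest autosome in SW480, at 5524, and in LoVo, at 4231. LoVo had 2962 on chromosome 20, with its lowest autosome at 2530. Low ratios of DLD1 on 7p, 7q and 12p, and of LoVo on 20q, may therefore not be losses. With the mean of the other 3 lines as the reference the total rose from 21 to 43 arms, 15 in CaCo2, 12 in LoVo, 9 in SW480 and 7 in DLD1.

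**Figure D4:**
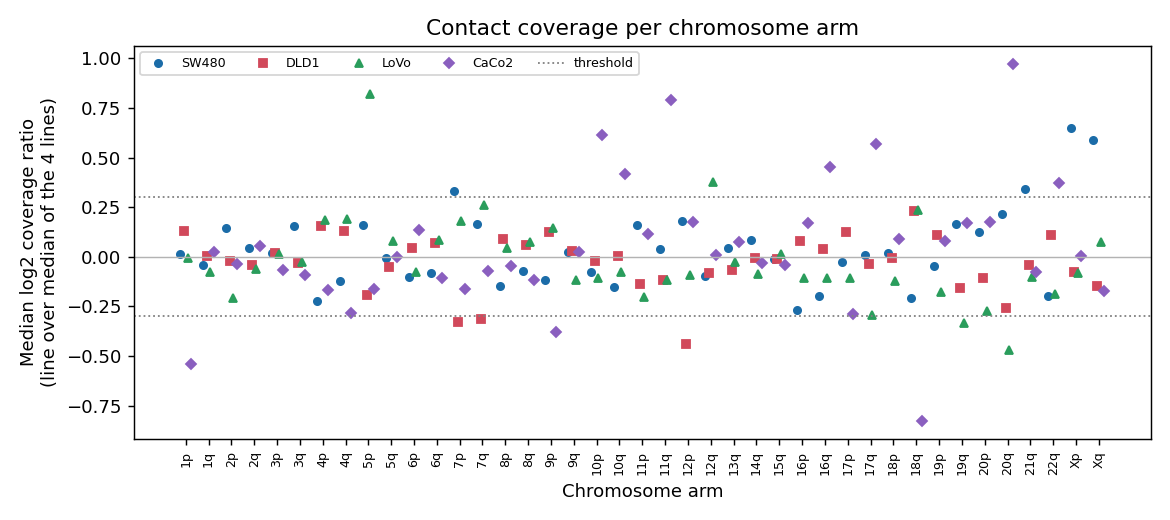
Median log2 coverage ratio (vertical axis) of each chromosome arm (horizontal axis), 1 marker per line, with dotted lines at 0.3 in both directions. CaCo2 reaches 0.97 on 20q and -0.83 on 18q, and LoVo 0.82 on 5p.

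Runs of 1 Mb bins beyond a log2 ratio of 1 numbered 33 in CaCo2, 6 in SW480, 3 in LoVo and 0 in DLD1. They are not all separate focal changes, since 31 of those in CaCo2, 3 in LoVo and 1 in SW480 lay on an arm whose median was itself at or beyond 0.3 in the same direction. With the median of the arm subtracted, an alternative added after the data were seen, 9 runs were left in CaCo2, 2 in SW480 and 0 in LoVo and DLD1. The most extreme was in SW480 on chromosome 8 from 126 to 130 Mb, where the peak bin reached 2.70, 6.50-fold the median of the lines. This is the long arm of chromosome 8, which carries the oncogene MYC, although genes were not placed on the maps. SW480 also had low coverage on chromosome 10 from 1 to 3 Mb (mean -1.26, most extreme bin -1.28) and high coverage on chromosome 12 from 26 to 27 Mb (1.16). LoVo had its runs on 5p, from 25 to 31 Mb, at 40 to 41 Mb and from 44 to 46 Mb, with peaks of 1.24, 1.03 and 1.24. CaCo2 had low coverage on chromosome 9 from 71 to 84 Mb (mean -1.70, most extreme bin -2.02) and from 24 to 27 Mb (mean -1.46, most extreme bin -1.60). Its coverage was high on chromosome 17 from 45 to 49 Mb (mean 1.49, most extreme bin 1.68). The SW480 run on Xq from 99 to 100 Mb (1.05) overlapped its positive line-specific region from 98.6 to 99.6 Mb. The CaCo2 run on 17q from 26 to 27 Mb (1.58) overlapped its positive region from 26.0 to 26.6 Mb. These runs need not mark copy number, and the other runs overlapped no line-specific region of their line. The total of 42 runs became 91 at a threshold of 0.8 and 13 at 1.2.

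**Figure D5:**
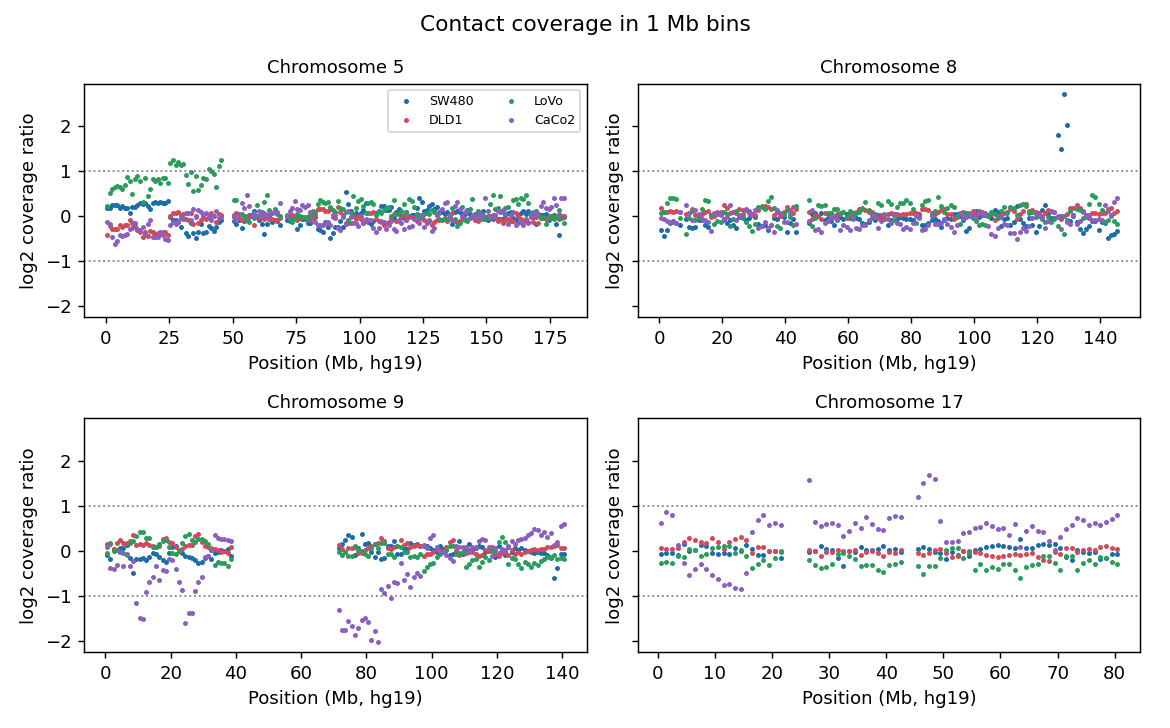
Log2 coverage ratio (vertical axis) of 1 Mb bins along chromosomes 5, 8, 9 and 17 (horizontal axis, Mb in hg19), with 1 colour per line and dotted lines at 1 and -1. SW480 reaches 2.70 on chromosome 8, and CaCo2 falls to -2.02 on chromosome 9.

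Clusters of contacts between chromosomes were found in SW480 and CaCo2. Contacts and ratios below are summed over the pairs of 1 Mb bins that passed the thresholds, not over whole segments, so ratios of at least 5 are set by the rule. The sparse maps held 0.0622 to 0.0945 contacts per pair on average, so 1 contact there usually exceeded 2 times. Absence from the sparse maps is thus largely built into the rule. In SW480, 7 pairs of bins joined the high-coverage segment of chromosome 8 from 126 to 130 Mb and chromosome 19 from 43 to 45 Mb. They held 300 recovered contacts, against 9.58 expected (31.3 times, Poisson interval 27.9 to 35.05). Another 4 pairs of bins joined chromosome 5 from 93 to 95 Mb and chromosome 20 from 16 to 20 Mb. They held 171 contacts, against 2.06 expected (82.9 times, 70.9 to 96.3). The chromosome 5 side holds the SW480 boundary named above. SW480 coverage also changed there, from -0.25 in the bin at 93 Mb to 0.52 in that at 94 Mb. Whether this boundary is the edge of a domain or of a rearranged segment was not tested. CaCo2 had 39 clusters. The largest lay between chromosome 2 from 177 to 226 Mb and chromosome 9 from 97 to 127 Mb (390 pairs of bins, 50348 contacts, 8.26 times expected). The next lay between chromosome 9 from 0 to 42 Mb and chromosome 15 from 20 to 34 Mb (301 pairs of bins, 9.50 times). The third lay between chromosome 11 from 66 to 75 Mb and chromosome 17 from 45 to 49 Mb (18 pairs, 7.01 times). The chromosome 17 side is the segment with high coverage.

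The number of clusters cannot be compared between CaCo2 and the other lines, since their maps hold 0.195% to 0.224% of contacts between chromosomes. With such contacts thinned to the LoVo number, CaCo2 had 0 clusters and SW480 had 1, and at a minimum of 40 contacts SW480 had 0. Of the 39 in CaCo2, 21, that of chromosomes 9 and 15 among them, reached within 3 Mb of a centromere, where sequence is shared between chromosomes. Whole arms gave more for the sparse maps, an analysis added after the data were seen. Numbers and ratios of arm pairs cannot be compared with CaCo2 either. In the sparse maps they rest on the 0.195% to 0.224% of contacts named above, which may not represent all contacts between chromosomes. In SW480, 12 of 802 pairs of arms had at least 2 times the expected contacts and under 1.5 times in the other lines, led by 10p with 12q (5.00 times, Poisson interval 4.79 to 5.23) and 5q with 20p (4.22 times). LoVo had 2 such pairs, 2q with 12p (3.38 times) and 2q with 12q (2.46 times), DLD1 had 6p with 11p (2.74 times), and CaCo2 had 2, 2q with 9q (2.41 times) and 9p with 15q (2.08 times).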

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

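The 4 lines carry the same source label and were screened as 1 set with Dixon's ratio in 14 summary measures. By chance about 1 in 20 such sets has a value this far from the rest, and 2 were found. The test of the first was written before its result was seen, with a second measure, left out here because it is divided by the contacts between chromosomes and so restates the result.

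CaCo2 stood apart in the share of contacts between chromosomes, 28.8% against 0.195% to 0.224% in the other 3 maps. If contacts between chromosomes had been removed in processing, contacts at 100 Mb or more within chromosomes would remain at ordinary levels in the sparse maps. They did: their share was 0.670 to 0.732 times that of CaCo2. Removal in processing is consistent with these values and is the candidate explanation. No biological explanation was tested.

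CaCo2 also stood apart in the number of arms with changed coverage, 10 against 3 or 4 in the other lines. This depended on the settings. CaCo2 had the most in each, but Dixon's ratio fell from 0.857 to 0.375 against the mean of the other 3 lines (15 against 7 to 12), 0.286 at a threshold of 0.2 (12 against 5 to 10) and 0.750 on contacts between chromosomes only, all below the critical value. It stayed at 0.857 on contacts within chromosomes only and at a threshold of 0.4.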

How the results depend on the processing

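Alternatives added after the data were seen are the recovered contacts for decay, the subtracted background, chromosomes 21 and 22 left out, the common score distribution, the 50% coverage minimum for regions, the subtracted arm median for coverage runs, both for compartment strength, and those on other-line contacts, the LoVo number, centromeres and arm pairs for clusters. Of 441 values under alternatives, 279 stayed within the tolerance, 158 moved and 4 changed sign. Among those of results marked as headline results, more moved than stayed, 56 against 40. Among the rest 239 stayed, 102 moved and 4 changed sign. The tolerance was counting error for shares, correlations and scores, the SD over chromosomes for slopes and strength, the SD over bins for coverage ratios, and 1.5 times for counts. Except where a threshold, bin size or depth changes a count by construction, the cause was not tested. The gene list alternatives were not run.

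The CaCo2 share between chromosomes was 28.6% over usable bins and 33.2% without contacts within a bin. The share under 2 Mb was 59.97% in SW480, 62.5% in DLD1, 54.79% in LoVo and 57.9% in CaCo2 on recovered contacts, and 59.5%, 62.3%, 54.80% and 57.4% after balancing again. The DLD1 slope was -1.25 from 1 to 10 Mb, and with the background subtracted the slopes were -1.19 in SW480 and -1.193 in CaCo2. The mean compartment correlation of the 6 pairs was 0.871 on recovered contacts, 0.879 with 400 kb bins, 0.873 at a 50% coverage minimum, 0.87885 with the first eigenvector and 0.8785 without chromosomes 21 and 22, and SW480 and DLD1 were the most distant pair in each. Line-specific regions numbered 223 with 400 kb bins, where 1 bin was enough, and 29 at a distance of 1.5.

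The distance of the 22q region of SW480 to the nearest line changed sign, to -0.0101 on recovered contacts, -0.00312 at a 50% coverage minimum and -0.166 with the first eigenvector, and that of the Xp region of LoVo to -0.628 at the 50% minimum. The mean boundary match was 82.0% with a 240 kb window, 75.1% with 960 kb, 77.6% at a prominence of 0.4, 58.6% in the same bin, 83.2% within 2 bins and 76.9% on recovered contacts. The share of boundaries at a compartment change in SW480, DLD1, LoVo and CaCo2 was 29.6%, 32.4%, 37.3% and 27.4% at a prominence of 0.4. It was 22.8%, 25.4%, 27.1% and 22.1% with a 240 kb window, 28.7%, 31.3%, 36.6% and 27.6% with 960 kb, and 28.6%, 31.8%, 33.8% and 27.5% with 400 kb compartment bins.

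Arms with changed coverage numbered 43 against the mean of the other 3 lines, 35 at a threshold of 0.2 and 13 at 0.4, and coverage runs 91 at 0.8, 13 at 1.2 and 11 with the median of the arm subtracted. Clusters numbered 151 at 3 times expected, 16 at 10 times, 75 at 10 contacts and 27 at 40. They numbered 67 where under 3 contacts in another line passed, 1 at the LoVo number, 20 away from centromeres and 17 as pairs of arms.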

Other observations

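Compartments were separated least in the CaCo2 map. Contacts between bins of the same kind, over those between the top and bottom 20% of scores at 2 to 50 Mb, gave a strength of 4.51 in DLD1, 4.12 in SW480, 4.10 in LoVo and 3.08 in CaCo2. The SDs over autosomes were 0.715 to 1.05 in DLD1, SW480 and LoVo, wider than the gaps among them, and 0.363 in CaCo2. The order follows the number of contacts within chromosomes. With these thinned to the CaCo2 number and the scores computed again the values were 4.43 in DLD1, 4.10 in SW480 and 4.08 in LoVo, and without chromosomes 21 and 22 CaCo2 was at 3.08. Both settings were added after the result was seen. In CaCo2 contacts between the top and bottom 20% were 0.504 times the mean at their distance, against 0.378 to 0.408 in the other lines. Its map also held 28.8% of contacts between chromosomes, against 0.195% to 0.224%, and was balanced over a different set of contacts. Whether this processing, or a background of random ligation, lowers the strength was not tested. The low value may therefore not be a trait of the line. Contacts among the lowest-scoring bins were most enriched in SW480, 1.86 times the mean at their distance, and those among the highest-scoring bins in DLD1, 1.63 times.

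The tests of depth below were chosen after the result was seen, and the other tests were not.

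In SW480 and DLD1 together, 54 of 65 line-specific regions, 83.1%, had a positive score. These lines were put together because of their counts, so the intervals below do not test the grouping. With 400 kb bins, where 1 bin was enough, both had more negative regions, as given above, and the share at that setting is not given here. With the scores of all lines given the same distribution the share was 79.4% (exact binomial interval 67.3 to 88.5), which argues against skewed score distributions. With the contacts within chromosomes of every map, the only ones the scores are computed from, thinned to the same number it was 83.1% (71.7 to 91.2), which argues against their depth. Changed coverage was found in 43 of 194 bins of these regions, of either sign, against 28.8 expected, a ratio of 1.49 (Poisson interval 1.08 to 2.01). Neighbouring 200 kb bins share a 1 Mb coverage value, so they are not independent and the interval is too narrow. The count does not separate positive from negative regions, nor an effect of copy number on scores from one of compartment on coverage. It therefore cannot decide whether copy number changes contribute to the positive share. A difference between the lines themselves stays open as untested.

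LoVo had the flattest decay, with a gap of 0.0653 in slope to the nearest line. After the mean contact at 100 Mb or more was subtracted the gap was 0.0812, which argues against a background of random ligation as the whole source. LoVo was flattest on 20 of 22 autosomes, which argues against a few rearranged chromosomes. Thinning lowers the mean contact at every distance alike, so the gap of 0.0653 in thinned maps decides nothing on depth. A difference between the lines, or between their libraries, may lie behind it and cannot be separated with 1 library each.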
